A study of Homo sapiens with 6 samples.

How the data were processed

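Chromatin of ME-1 cells was precipitated with antibodies against H3K27ac or RUNX1 after 6 h in DMSO or AI-10-49 (1 µM), and was sequenced with single-end Illumina reads, per the labels. Of 6 libraries, 4 had a peak list and were used. The 2 input libraries (DMSO and AI-10-49) were not used here directly. Groups were taken from the sample titles, and each antibody and condition had 1 library.

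The submitters' processing notes name CASAVA 1.4, Bowtie2 2.1.0, SAMtools 1.3, Picard 1.96 and MACS2 2.1.0 and the build hg19, without the role or order of each tool. Peaks were listed per sample, and which input entered each call is not given in the sources used here. Each deposited list gives a position and summit for each peak. The deposited ratio per peak is the fold enrichment at the summit over the local background, as the authors' MACS2 run gave it. The deposited −log10 p and −log10 q values per peak are also the authors'. The deposited score per peak was not used here. The lowest −log10 q was 1.31 in each list of RUNX1 DMSO, H3K27ac DMSO and H3K27ac AI-10-49 and 1.36 in RUNX1 AI-10-49, as a q threshold of 0.05 gives. The lists held no peak outside chromosomes 1 to 22, X and Y, none past the end of its hg19 chromosome, and no overlapping intervals.

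Summit fragment numbers were recovered from the deposited values. MACS2 tests the scaled number of fragments over a summit against a Poisson background, so fold enrichment and −log10 p together give both numbers once the factor that scales the ChIP library to its input is known. For each list the factor was sought at which the fragment numbers came out whole. All peaks were then solved to within 0.003 of their −log10 p (100% in each list), against a median of 1.33% to 2.67% at other factors. The read totals follow from the lowest background, a genome size of 2700000000 bp (the human preset of MACS2, assumed) and the shortest peak, taken as the fragment length (192, 210, 149 and 169 bp for H3K27ac DMSO, H3K27ac AI-10-49, RUNX1 DMSO and RUNX1 AI-10-49). Ratios between libraries do not depend on the preset if it was the same for all. Each input was estimated from both antibodies' lists, and these estimates differed by 0.00741% (DMSO) and 4.17e-05% (AI-10-49). In data simulated for the 4 lists (1496, 2967, 2977 and 2953 peaks) 100% of the fragment numbers were exact, and 0 of 7038 overlap calls on simulated intervals differed from bedtools 2.31.1.

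Fragments per M reads are summit fragments over the recovered ChIP reads. Where a DMSO peak overlapped several AI-10-49 peaks, the one with most fragments was taken. An AI-10-49 peak that overlapped several DMSO peaks was paired with each of them. Because a longer fragment covers a summit more often, the ratio of fragment lengths (1.13 for RUNX1, 1.09 for H3K27ac) bears on every ratio of fragments. Ratios are not corrected for it, except where RUNX1 peaks with at least 2 fragments per M reads were counted.

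Peaks were shared if they overlapped by at least 1 bp. Shares carry exact Clopper-Pearson intervals (95%), and fragment numbers carry exact Poisson intervals. Chance overlap came from 1000 random placements on the same chromosome. H3K27ac regions of 1 list only were set against 1000 sets of regions in both lists, matched on width and −log10 q, each rounded on the log2 scale. No test between conditions was made, since each had 1 library. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9.

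Named regions were chosen by rules fixed before the data were examined. These were the 15 AI-10-49-only, 5 DMSO-only and 5 shared RUNX1 peaks and the 10 H3K27ac regions of each list only with the highest −log10 q. To these came the 5 highest AI-10-49-only RUNX1 peaks in H3K27ac regions of each list only, the bands of MYC, RUNX1, CBFB and MYH11, and the peaks of the MYC band. The H3K27ac regions compared by fragment number within that band were chosen after their values were seen, as was the mention of GATA2 and BIRC3.

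Positions are given 1-based in hg19 with the cytoband (table of circlize 0.4.16, whose chromosome ends equal the hg19 lengths in GenomeInfoDb 1.38.1). The gene table at hand was of another build, GRCh38.p14, so no gene was assigned to a peak, and whether a region is exonic, intronic or intergenic is not given. A gene named beside a band is background and does not place the peak at the gene. Counts of gene lists near peaks and of the RUNX motif at summits were planned for an hg19 annotation and sequence and were not analysed here. The MYC region was its cytoband, 8q24.21, for the same reason. Alternatives for overlap, threshold, list length, contigs, unit and depth were fixed beforehand.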

Results

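ME-1 is an established human leukemia cell line that carries inv(16), the inversion of chromosome 16 that joins CBFB to MYH11 and makes the fusion protein CBFβ-SMMHC. The fusion protein binds RUNX1, a transcription factor of blood cell development whose normal partner is CBFβ. AI-10-49 is a small molecule that inhibits the binding of CBFβ-SMMHC to RUNX1. Cells were given AI-10-49 at 1 µM or DMSO for 6 h, and chromatin was precipitated with an antibody against RUNX1 or against H3K27ac, the acetylation of histone H3 found at active promoters and enhancers. The series held 6 libraries, of which 4 had a peak list (RUNX1 and H3K27ac, DMSO and AI-10-49), while the 2 input libraries had none. Each antibody and condition had 1 library. No difference between conditions could therefore be set against a replicate spread, and no p-value is given. Intervals on shares (exact Clopper-Pearson, 95%) cover the sampling of peaks, and intervals on fragment numbers cover counting error only.

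Depth was recovered from the peak lists. The RUNX1 libraries held 33.8 M (mega) reads for DMSO and 31.5 M for AI-10-49, a ratio of 0.933. For H3K27ac the estimates were 35.7 M reads (DMSO) and 37.0 M (AI-10-49), and for the inputs 34.0 M and 27.6 M. A list is limited by the smaller of its ChIP and input library, and by that measure the AI-10-49 lists had 0.816 (RUNX1) and 0.812 (H3K27ac) of the depth of the DMSO lists.

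The first comparison asks how RUNX1 occupancy differed after 6 h of AI-10-49. RUNX1 was called at 1701 sites in DMSO and at 10319 sites in AI-10-49, a ratio of 6.07, and the covered sequence was 0.394 Mb and 3.49 Mb. Of the DMSO sites, 1551 (91.2%, 89.7 to 92.5) overlapped a site of the AI-10-49 list, against 0.230% on average for sites placed at random. Random placement ran over whole chromosomes, without regard to acetylated chromatin. As a closer reference, 13.8% of DMSO H3K27ac regions overlapped an AI-10-49 RUNX1 site. The AI-10-49 list held 8783 sites that overlapped no DMSO site, and 150 DMSO sites overlapped no AI-10-49 site. Of the 1551 DMSO sites in both lists, 1392 (89.7%) had more summit fragments per M reads in AI-10-49 than the longer fragments of that library (1.13 times) would give. The median ratio was 2.1 (quartiles 1.52 and 2.97).

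**Figure D1:**
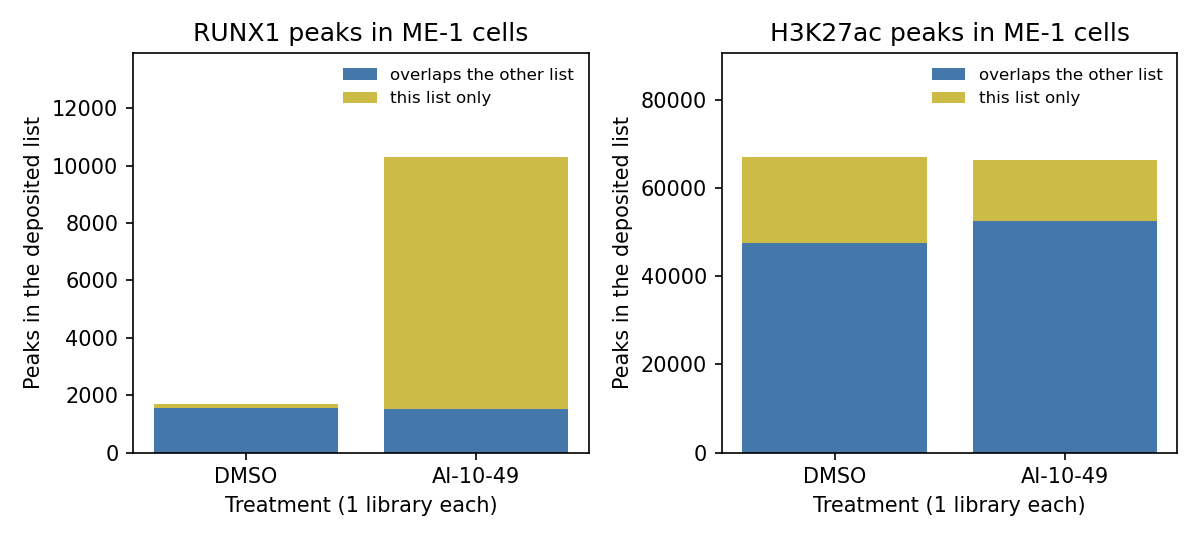
Number of peaks (y axis) in the deposited list of each treatment (x axis, 1 library per bar) for RUNX1 (left) and H3K27ac (right), split into peaks that overlap the other list of the same antibody and peaks of that list only. RUNX1 has 1701 peaks in DMSO and 10319 in AI-10-49, and H3K27ac has 67087 and 66350.

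Fold enrichments and −log10 q values of single peaks are the authors' own and rank peaks within their list only. The AI-10-49-only site with the highest −log10 q (186) lay in 8q22.3 at chr8:103665814-103667049 (hg19, as all positions here), with a fold enrichment of 32.4 and 183 fragments over the summit. It was 152 kb from the nearest DMSO site. Sites in 2p23.2 (chr2:28632885-28633626, fold 33.3), 15q25.1 (chr15:80935756-80936445, fold 33.0) and 11q13.4 (chr11:72447309-72448200, fold 13.0 over a high background) came next. The largest fold enrichment among the 15 named AI-10-49-only sites was 38.9, in 6q25.3 at chr6:159070546-159071195, 618 kb from a DMSO site. These 15 sites lay on 11 chromosomes, held 129 to 236 summit fragments, and each overlapped an H3K27ac region of both conditions. With a margin of 1 kb, 14 of the 15 still had no DMSO site, the exception being the 2p23.2 site at 0.436 kb.

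The sites named from both lists ranked highest in the AI-10-49 list. A site in 14q11.2 (chr14:23025057-23025753) had 286 summit fragments and a fold enrichment of 31.4, and a site in 8p21.3 (chr8:22562208-22563077) had 298 fragments and a fold of 23.8. Sites in 14q32.12 (chr14:93143358-93143999), 12p13.31 (chr12:7062567-7063433) and 6q14.2 (chr6:84152389-84152950) had folds of 46.1, 31.6 and 45.5. DMSO-only sites were weaker within their own list, with a median −log10 q of 6.94 against 10.2 for DMSO sites in both lists. The foremost of them, in 10p15.3 (chr10:1295829-1296350), had 64 fragments and a fold of 12.3 and lay 172 kb from an AI-10-49 site. The other named DMSO-only sites, in 16p13.3, 7q21.2, 3p21.31 and 19p13.3, had folds of 5.33 to 7.66, and those of 7q21.2 and 19p13.3 lay within 1 kb of an AI-10-49 site.

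The larger number in AI-10-49 was spread over the genome. All 485 cytobands with at least 50 DMSO H3K27ac regions held more RUNX1 sites in AI-10-49 than in DMSO. In 21q22.12, the band of RUNX1 itself, sites numbered 4 in DMSO and 20 in AI-10-49. The band of CBFB, 16q22.1, had 7 and 25, and 16p13.11, the band of MYH11, had 2 and 11. Sharing depended on how it was counted. With at least 50% of both intervals required, 49.5% of DMSO and 8.16% of AI-10-49 sites were shared, and between equally long lists of the highest-ranked sites 48.3% and 47.4% were.

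The second comparison asks which acetylated regions differed. H3K27ac was called in 67087 regions in DMSO and 66350 in AI-10-49, a ratio of 0.989, covering 68.7 Mb and 62.4 Mb. Of the DMSO regions 47607 (71.0%, 70.6 to 71.3) overlapped an AI-10-49 region, and of the AI-10-49 regions 52448 (79.0%, 78.7 to 79.4) overlapped a DMSO region. Random placement gave 3.86% and 4.08%. Regions in DMSO only numbered 19480 and regions in AI-10-49 only 13902. Among regions with a −log10 q of at least 10, 2777 were in DMSO only and 447 in AI-10-49 only.

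The DMSO-only region with the highest −log10 q lay in 13q14.11 (chr13:40845739-40846749), with a fold enrichment of 18.5 and 96 summit fragments, 64.2 kb from the nearest AI-10-49 region. Regions in 11p15.5 (chr11:1901424-1903852, fold 12.9), 16p13.3 (chr16:1169438-1170236, fold 13.7) and 5q35.3 (chr5:180074827-180077412, fold 15.7) followed. Another lay in 3q21.3 (chr3:128273633-128276250, 101 fragments, fold 13.6), the band of GATA2, a regulator of blood stem and progenitor cells. The others lay in 2p25.3, 2p13.2, 14q32.33, 13q34 and 17q21.2, and the 2p13.2 region was 0.222 kb from an AI-10-49 region. Among AI-10-49-only regions the first was chr19:50264564-50265102 in 19q13.33, with a fold of 10.6 and 56 fragments, only 0.054 kb from a DMSO region. Regions in 15q24.3 (chr15:78151078-78151404, fold 10.6, 54 fragments) and 7q36.3 (chr7:157725025-157726836, fold 11, 50 fragments) were 32.0 kb and 77.3 kb from one. Of the 10 named AI-10-49-only regions, 6 had no DMSO region within 1 kb, and of the 10 DMSO-only regions 9 had no AI-10-49 region there.

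Regions in both lists held a median of 1.15 summit fragments per M reads in DMSO and 1.05 in AI-10-49, and the median ratio was 0.838 (quartiles 0.634 and 1.16). The longer fragments of the AI-10-49 library would give 1.09, and 28.9% of these regions lay above that. With at least 50% of both intervals required, 46.4% of DMSO and 47.0% of AI-10-49 regions were shared, and 51.9% of either list were when the top 1000 regions were compared.

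The third comparison places the RUNX1 sites in acetylated chromatin. In DMSO 81.8% (79.9 to 83.6) of RUNX1 sites overlapped an H3K27ac region of DMSO, and in AI-10-49 86.1% (85.4 to 86.7) overlapped one of AI-10-49. Counted by summits inside a region, the shares were 69.4% (67.1 to 71.6) and 68.4% (67.5 to 69.3), with overlapping intervals. Within 1 H3K27ac list the AI-10-49 summits were inside more often, with 76.2% against 69.4% in DMSO regions and 68.4% against 59.3% in AI-10-49 regions. Sites of AI-10-49 only lay in chromatin that was already acetylated in DMSO in 90.5% of cases (89.8 to 91.1). Of the 150 DMSO-only sites, 70.0% (62.0 to 77.2) overlapped a DMSO region and 54.7% (46.3 to 62.8) an AI-10-49 region. Only 692 AI-10-49-only sites lay in no H3K27ac region of either list.

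H3K27ac regions listed in 1 condition only seldom held a RUNX1 site. An AI-10-49 RUNX1 site lay in 18.5% of DMSO regions found in both lists and in 2.41% (2.20 to 2.64) of DMSO-only regions. Sets of shared regions of similar width and −log10 q, each rounded to a whole log2 unit, gave 3.44% on average, and the lowest of 1000 sets gave 3.01%. Differences in width and −log10 q inside these classes were not removed and may bear on so small a gap. Among AI-10-49-only regions the share was 0.993% (0.835 to 1.17), against 3.41% on average and 2.92% at the lowest in matched sets. AI-10-49-only RUNX1 sites in a DMSO-only region numbered 313, led by sites in 17q11.2 (chr17:25871558-25871988, fold 21.1), 5q33.3 (chr5:158839317-158839850, fold 25.3) and 10q25.1 (chr10:108579316-108579642, fold 28.3). The 17q11.2 and 10q25.1 sites also overlapped an AI-10-49 region, and the 5q33.3 site did not. Those in an AI-10-49-only region numbered 109. Their first was in 11q22.2 (chr11:102187842-102188454, fold 24, 136 fragments), the band of the apoptosis inhibitor gene BIRC3, where it touched a DMSO region and a named AI-10-49-only region. The 17q11.2 site came next in this class too, since it overlapped a region of each kind. Others were in 13q34 (chr13:111073997-111074482, fold 25.5) and 16p12.1 (chr16:27442305-27442724, fold 19.1). With both H3K27ac lists cut at a −log10 q of at least 5, the shares holding a RUNX1 site were 3.94% (DMSO only) and 2.11% (AI-10-49 only). Regions of 1 list only then include some that overlap a weaker region of the other list, so these are not the same classes.

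The title of the series names MYC chromatin, so the cytoband of MYC was examined region by region. MYC, which encodes a transcription factor of cell growth, and its neighbour PVT1 lie in 8q24.21. This band held 4 RUNX1 sites in DMSO and 22 in AI-10-49, and all 4 DMSO sites were among those overlapped. The 4 had more summit fragments in AI-10-49, with counting intervals that did not meet. At chr8:128929516-128930351 (interval of the AI-10-49 list) fragments per M reads were 1.6 (1.2 to 2.09) in DMSO and 4.51 (3.79 to 5.31) in AI-10-49. At chr8:129263385-129263860 the values were 0.859 (0.575 to 1.23) and 3.74 (3.10 to 4.48). The site with most fragments, chr8:130593849-130594801, had 1.42 (1.05 to 1.88) and 5.27 (4.5 to 6.13), and chr8:131296644-131297281 had 0.799 (0.527 to 1.16) and 2.98 (2.41 to 3.65).

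**Figure D2:**
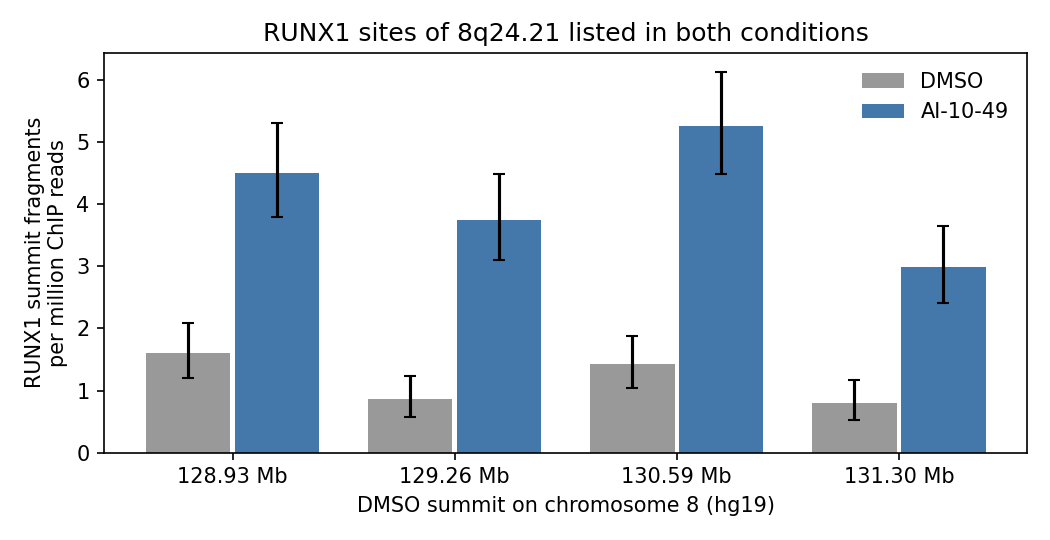
RUNX1 summit fragments per M ChIP reads (y axis) at the 4 sites of 8q24.21 listed in both conditions, placed by DMSO summit on chromosome 8 (x axis, Mb, hg19); bars are single libraries and error bars 95% Poisson intervals of the count. The bars at chr8:130593849-130594801 stand at 1.42 for DMSO and 5.27 for AI-10-49.

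The other 18 RUNX1 sites of the band were in the AI-10-49 list only. The strongest by −log10 q were chr8:130678635-130678995 (85 fragments, fold 7.54), chr8:130648211-130648608 (56 fragments, fold 11) and chr8:129279803-129280162 (46 fragments, fold 10.3). A weak site at chr8:128747324-128747637 (26 fragments, fold 3.96) lay inside the wide acetylated region chr8:128746422-128752169. For its number of H3K27ac regions the band was ordinary, with 14.8 AI-10-49 RUNX1 sites per 100 DMSO regions and a median of 14.6 over the 485 bands.

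H3K27ac covered 150 kb of 8q24.21 in DMSO (149 regions) and 144 kb in AI-10-49 (144 regions), with 46 regions in DMSO only and 30 in AI-10-49 only. No DMSO-only region of the band held an AI-10-49 RUNX1 site, and genome-wide only 2.41% of DMSO-only regions did. Over the 103 DMSO regions of the band that were in both lists, the median ratio of H3K27ac summit fragments was 0.971, where longer fragments alone would give 1.09. Ranked among regions of similar summit count genome-wide, 14 of the 103 lay above percentile 85 and 6 below percentile 15, where an even spread would put 15% in each tail. Some of the 14 took the summit of a wide AI-10-49 region that also covered neighbouring DMSO regions. For example, chr8:131004436-131005536 and chr8:131005594-131005804 both took 4.22 fragments per M reads from a summit at chr8:131007209, outside both. The count of 14 is therefore no measure of raised acetylation. In chr8:128746422-128752169 the H3K27ac summit held 6.22 fragments per M reads in DMSO and 3.24 in AI-10-49, a ratio of 0.522, at percentile 13 among 3369 regions of similar summit count. In chr8:130674331-130682196 the values were 7.0 and 3.81 (percentile 11.5), and in chr8:130591779-130598588 they were 6.72 and 3.89 (percentile 18.8). A weaker region, chr8:128806802-128809005, had 2.0 and 0.676, a ratio of 0.345 at percentile 2.53, and chr8:131006470-131009119 had 4.34 and 4.22 at percentile 93.3. The AI-10-49-only region chr8:131335926-131336946 (55 fragments, fold 9.15) was among the 10 named for the whole genome. At a −log10 q of at least 10 the band held 62 and 57 H3K27ac regions.

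**Figure D3:**
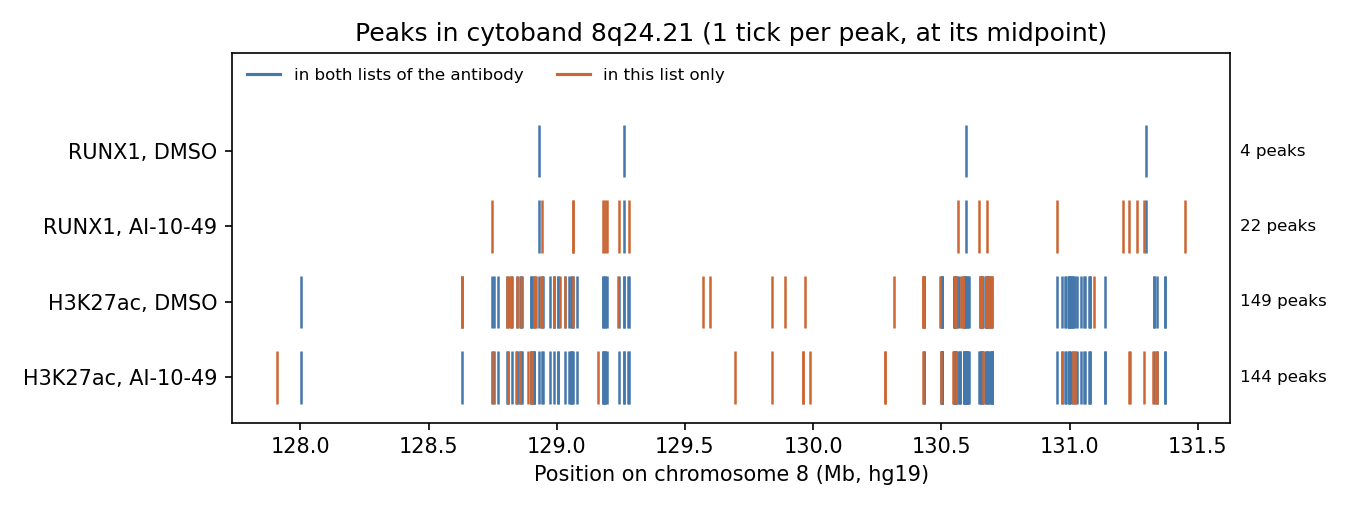
Peaks of the 4 lists along cytoband 8q24.21 (x axis, position on chromosome 8 in Mb, hg19), 1 tick per peak at its midpoint, coloured by whether the peak overlaps the other list of the same antibody. RUNX1 has 4 ticks in DMSO and 22 in AI-10-49, and H3K27ac has 149 and 144.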

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

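The settings with a common −log10 p threshold or with at least 2 summit fragments per M reads were chosen after seeing the data. Other settings moved how many peaks counted as shared, and no ratio of list lengths crossed 1. Of 87 alternative values 48 stayed close (inside the interval of a share, or within 1.5 times of a ratio or count) and 39 moved. The 48 include values that could only repeat the main result. These came from counting all contigs or rows as deposited, and from the DMSO share in H3K27ac with equal RUNX1 list lengths. The 48 are therefore no measure of stability. Except as given, the cause was not tested. The ratio of RUNX1 peak numbers (6.07) lay between 6.04 and 7.81 with common thresholds and rescaled depth, and was 15.9 with at least 2 fragments per M reads. Shares below are for DMSO, then AI-10-49.

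For RUNX1 (91.2% and 14.9% shared), 50% of both intervals gave 49.5% and 8.16%, where the wider AI-10-49 peaks lower the share by construction. Summits within 250 bp gave 88.4% for DMSO, and a 1 kb margin 16.4% for AI-10-49. A −log10 q of at least 10 gave 11.7% for AI-10-49, and at least 5 against the full other list 92.8% and 16.2%. Equal list lengths gave 48.3% and 47.4%, the top 1000 44% and 43%, since these drop most AI-10-49 peaks, and 2 fragments per M reads 94.8% and 5.97%.

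For H3K27ac (71.0% and 79.0%), 50% of both intervals gave 46.4% and 47.0%, summits within 250 bp 54.8% and 55.4%, and a 1 kb margin 83.5% and 90.0%. A −log10 q of at least 5 gave 84.6% and at least 10 91.8% for AI-10-49. At least 5 against the full other list gave 80.2% and 89.6%, and the top 1000 51.9% and 51.9%.

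RUNX1 peaks in H3K27ac (81.8% and 86.1%) came to 79.7% and 84.0% with H3K27ac −log10 q of at least 5, 69.4% and 68.4% with the summit inside, and 87.1% and 90.1% within 1 kb. Equal list lengths gave 90.5% for AI-10-49. H3K27ac regions of 1 list only with a RUNX1 peak (2.41% and 0.993%) came to 0.477% and 0.230% with the shorter RUNX1 list. They came to 3.94% and 2.11% with both H3K27ac lists cut at −log10 q of at least 5, which also changes which regions are of 1 list only. In 8q24.21, 62 and 57 H3K27ac regions were left at −log10 q of at least 10.

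Counting all contigs or rows as deposited changed nothing, since no peak was concerned. Gene lists near peaks, the RUNX motif and other extents of the MYC region were not run, each with its alternatives, for lack of an hg19 annotation and sequence here. No paired analysis was possible because each condition had 1 library.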

Other observations

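The tests on the yield of the RUNX1 precipitation, on the general shrinkage of the H3K27ac list, and on acetylation at RUNX1 sites and in the MYC band were chosen only after the result was seen, and those with a common −log10 p threshold or with 2 summit fragments per M reads after the list lengths were. RUNX1 sites of AI-10-49 were densest, among the 485 bands with at least 50 DMSO H3K27ac regions and relative to these, in 15q24.2 (41.9 per 100 regions), 6q27 (34.8) and 1q22 (33.9), and the median over these bands was 14.6. In 15q24.2 RUNX1 sites numbered 8 in DMSO and 26 in AI-10-49, and in 1q22 10 and 38. By chromosome, the ratio of RUNX1 sites lay between 4.11 (chromosome 20) and 8.92 (chromosome 12). These bands and chromosomes were chosen after their values were seen. Strong H3K27ac regions in DMSO only (−log10 q of at least 10) numbered 22 of 88 in 14q32.33, the band of the immunoglobulin heavy chain genes, where an even spread gives 7.16. This band was picked for the largest excess (14.8) among 791 bands. The largest excess of any band in 1000 random spreads was 21.4, so by that measure the pick did not exceed every random spread. Bands with more strong regions can set that value, and 14q32.33 itself reached at most 17 in its random spreads. Taken band by band, 7 bands were above each of their own random values for DMSO only, and 0 of 785 for AI-10-49 only. The background under H3K27ac regions, relative to the autosomal median, was 1.46 (DMSO) and 1.59 (AI-10-49) on chromosome 11, 1.52 and 1.59 on chromosome 20, and 0.667 and 0.681 on chromosome 9. Chromosomes 8, 18, 19 and 22 were raised as well, at 1.27 to 1.46. The AI-10-49 value of chromosome 9 was the genome-wide lowest background of that list (2.14 fragments), so a lower local background there would not show.

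The longer RUNX1 list after AI-10-49 was weighed against a looser threshold, a lower input background and a higher yield. At the same −log10 p threshold (4.98) the ratio of peak numbers was 6.04 (5.74 to 6.37), which argues against a looser threshold. The ranges of this ratio and the next treat listed peaks as independent counts and hold no spread between libraries. Of the listed peaks, 77 in DMSO and 1222 in AI-10-49 reached 2 summit fragments per M reads, a ratio of 15.9 (12.6 to 20.2), which argues against a lower background. Peaks were called against the input, but a DMSO site with that many fragments would be missed only over a background above 39.2 fragments, which 1 of 67087 DMSO H3K27ac regions had. A higher yield of the treated precipitation cannot be told apart from more RUNX1 on the chromatin of treated cells, since each would raise the fragments at sites in both lists (median ratio 2.1) and only replicate precipitations could part them.

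Strong H3K27ac regions were in DMSO only more often than in AI-10-49 only, with 2750 against 470 at a −log10 p of at least 12. Rescaling the DMSO list to the depth of the AI-10-49 list left 1837 such regions (1754 to 1923, counting of regions only) against 480. Depth alone therefore does not account for the excess of strong regions. For regions of any strength the rescaling left 19226 in DMSO only against 14009. It lowered summit counts alone and kept 66635 of 67087 DMSO regions, so it could hardly show an effect of depth on weak regions. No conclusion is drawn for these. A uniform fall in yield was drawn by lowering 34062 strong DMSO regions by 0.705, the median factor of those in both lists, and lost at most 569 regions in 100 draws, against 2750 observed. The draws held counting noise alone, without the spread between separate precipitations, and the factor left out the regions that were lost, so the bound set beforehand was wrong and a uniform fall is not excluded. It cannot be told apart from a change of acetylation in treated cells without replicate precipitations.

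RUNX1 summits were inside H3K27ac intervals of AI-10-49 less often than inside those of DMSO (68.4% against 76.2% for AI-10-49 summits, 59.3% against 69.4% for DMSO summits). Of 7865 AI-10-49 RUNX1 summits inside a DMSO H3K27ac interval, 85.2% were inside an AI-10-49 interval. In 1000 sets of matched positions in regions without RUNX1 the share was 87.3% to 89.4%. These positions were matched on the width and −log10 q of their region, not on the H3K27ac signal at the position itself. A general shrinkage of the H3K27ac list could break intervals first where that signal was already low, so it is not excluded. Of the 1163 summits that left an interval, 66.0% lay between a pair of AI-10-49 intervals each within 1 kb, against 32.5% to 43.1% in the matched sets. An acetylation gap at the RUNX1 summit, as nucleosomes displaced there may leave, could give this, and so could shrinkage over a dip present in both conditions. From DMSO to AI-10-49 intervals, the share of summits inside fell from 77.6% to 70.0% at AI-10-49-only RUNX1 sites. At the 150 DMSO-only sites it fell from 62.0% to 43.3%, so the fall was not confined to sites listed in AI-10-49 only. As a hypothesis found on these data, a gap would need a map of nucleosomes or of open chromatin, and the displacement itself was not tested.

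A hypothesis that the H3K27ac summit count falls more in regions with an AI-10-49-only RUNX1 site found no support. The count was that of the highest AI-10-49 summit overlapping the region, which may lie away from the RUNX1 site. A fall confined to the RUNX1 site could be missed, so the test cannot decide on such a fall. Over 7935 DMSO H3K27ac regions with an AI-10-49-only RUNX1 site, with the 336 in DMSO only counted as the lowest, the median log2 ratio of summit fragments per M reads (AI-10-49 over DMSO) was -0.52. It lay above the range of -0.64 to -0.60 in 1000 sets of regions without RUNX1 matched on DMSO summit count and width. Over regions in both lists alone, matched on mean summit count and width, it was -0.49 and within the range of -0.51 to -0.47, so no difference is drawn from either. A further hypothesis, that acetylation falls more in the MYC band than elsewhere, found no support either by the same measure. Over the 149 DMSO regions of 8q24.21, counted likewise with 46 in DMSO only, the median was -0.32, within the range of -0.97 to -0.27 in matched sets from other bands, and the width of this range would hide a modest fall. Over the 103 in both lists it was -0.042, within -0.45 to 0.01. Single regions of the band that stood low, such as chr8:128746422-128752169 at a ratio of 0.522, are not answered by this median.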
